A study of Mus musculus with 8 samples.

How the data were processed

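RNA from immortalised mouse embryonic fibroblasts was measured on 8 Illumina mouse bead arrays. The labels give 4 groups of 2 arrays: total cytoplasmic RNA and heavy polysomal RNA (mRNA bound by more than 3 ribosomes) from 1 wild-type (WT) line and from 1 line with a knock-in of eIF4E that cannot be phosphorylated (KI). Per the labels, the embryos were at day 14.5 and the cells grew in DMEM with 10% serum. From each sample, 250 ng of RNA was labelled with biotin in a single round.

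The deposited values were processed by the authors and were taken here as log2 signal, since all were positive, most lay in a narrow band at the bottom and the top was near the limit of the scanner's range on a log2 scale. The labels name the R package lumi with no version, role or options. The log base, transform, background correction and normalization are not given in the sources used here, so a log2 fold change below holds only if the values are on a log2 scale. Array medians lay between 7.69 and 7.73, at the bottom of the signal range. A gene in that band has no measurable level, and folds against it are understated. With arrays, the number of arrays limits the precision.

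A second deposited table, named as non-normalized, held the same values in 8 columns (equal within 1e-06) under names that no label gives. Its 8 columns were not used, and the planned background correction and quantile normalization of unprocessed signal could not be run. The processed values of the labelled arrays were used instead.

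Each array held 25697 probes, of which 23978 had 1 gene symbol, 0 had several and 1719 had none. Of the named probes, 23962 were matched by gene ID to a reference annotation (RefSeq on the mouse assembly GRCm38.p6), which served for names and for the order of neighbouring genes. Probes were kept if their mean over the 8 arrays was above the median of the probe means, 7.73, which left 12848. Among these, 754 had no symbol and were set aside. Each gene was represented by its probe with the highest mean, which gave 8832 tested genes. More than 1 probe passed the filter for 2309 of them. The other probes of a gene did not always read the same difference, and for some genes they read far less.

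limma 3.58.1 in R 4.3.3 fitted 4 group means to all 8 arrays with no block, with lmFit and eBayes, so that the groups shared 1 estimate of the spread (4 residual and 1.8 prior degrees of freedom). Each p-value was two-sided and adjusted over the tested genes by the Benjamini-Hochberg method, and a gene passed at an adjusted p below 0.05. The comparisons were KI against WT in total RNA, KI against WT in polysomal RNA, the interaction of these, and polysomal against total RNA in each line. The interaction, called polysomal loading here, is the KI polysomal minus total difference less the WT one. Errors beside log2 fold changes are limma standard errors, with 2 arrays per group. All the p-values measure spread between experiments on 1 line of each genotype, so genotype and line cannot be told apart.

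A total of 31 gene lists covered the study's targets, translation, signalling, stress, matrix, metabolism and markers of cell types. The 27 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists of a comparison. With an estimated correlation 0 lists passed in any of the 5 comparisons. The smallest adjusted p with an estimated correlation was 0.243, in polysomal RNA. The study's targets (Ccl2, Ccl7, Mmp3, Vegfc, Birc2 and Nfkbia) were chosen by the study on these samples.

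The groups, tests, lists, most of the other settings tried and the rule for named genes were fixed before the data were examined. For KI against WT and for polysomal against total RNA in WT, the rule took passing genes whose arrays did not overlap between groups. Up to 10 with the largest rise and 10 with the largest fall were taken, leaving out clone and locus identifiers. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added up to 4 members of each list by smallest p, Eif4e, the study's targets and the sex-linked genes. Other genes named in the text were chosen after their values were seen, and the text says so there.

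Total and polysomal RNA of the same line and number share a source name in the labels, which was read as pairing by culture. Across genes, the deviations of total and polysomal RNA from their group means correlated at 0.58 in KI and 0.05 in WT. KI and WT arrays share only a number, and their deviations correlated at 0.39 in total and 0.24 in polysomal RNA; KI total with WT polysomal RNA gave 0.16 and WT total with KI polysomal RNA 0.10. Genes are not independent replicates, so no test was made of this pairing. The fixed culture block is given beside the comparisons of RNA types, and the replicate block among the alternatives.

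The fit was tested on simulated data with 200 changed genes in each of 5 simulations. At a log2 change of 1 it recovered 54.4% in total RNA, 57.6% in polysomal RNA and 35% in loading, with 11.6, 9.2 and 6.2 false calls on average. At a change of 2 it recovered 88.2%, 84% and 71.8%. The changed genes were drawn from all tested genes, and simulated falls could go below the bottom of the signal range, unlike real ones. The noise was independent between arrays, with no pairing by culture. The recovered shares can therefore be too high for real falls and for loading. The list test was run in 40 simulations of total RNA with the interferon-response list shifted by 0.5. Camera with the preset correlation called it in 40 and camera with the estimated correlation in 23. Without a shift 2 list calls were made. The simulated genes varied independently of each other, whereas the correlation estimated for this list in the data was 0.55. The simulation therefore cannot show how many false list calls the preset correlation makes on correlated genes.

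Alternatives changed the scaling between arrays, the filter, the treatment of several probes per gene, the variance model (trend and robust), the blocks, the fold minimum (1.5), the arrays in the fit and the model of loading, and left out each array in turn. Quantile normalization over all 8 arrays and list tests without each array, and without WT total replicate 2 with an estimated correlation, were chosen after seeing the data. No other splits of the samples were counted and no sample was tested as an outlier within its group, since each group held 2 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.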

Results

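The arrays compared fibroblasts with normal eIF4E and fibroblasts whose eIF4E cannot be phosphorylated. eIF4E binds the cap of an mRNA and recruits it to the ribosome, and the MNK kinases phosphorylate it. Total cytoplasmic and heavy polysomal RNA were measured in 2 independent experiments per line, which made 8 arrays in 4 groups of 2. The type of RNA separated the arrays most: the first principal component held 73.2% of the variance, the second 12.2%. Correlation across all probes, which are not independent replicates, was 0.991 between the WT polysomal arrays and 0.987 between the KI polysomal arrays. It was 0.975 between the KI total arrays and 0.970 between the WT total arrays. The array labelled WT total replicate 2 correlated at 0.982 with KI total replicate 2, above its value with WT total replicate 1. These 2 arrays share a replicate number, so their similarity cannot be ascribed to the line alone. The third component held 7.1% of the variance. It read 15.1 and 12.5 on WT and KI total replicate 2, and -11.7 and -19.8 on WT and KI total replicate 1.

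The first comparison asked how total RNA differed between the KI and the WT line. Genes of the Hoxb cluster, transcription factors that set position along the body axis, were lower in KI. Hoxb7 (probe ILMN_2946184) fell by 2.20 ± 0.14 on the log2 scale (SE, n = 2 arrays per group; limma adjusted p = 0.0277). Hoxb4 fell by 1.95 ± 0.17, Hoxb2 by 1.44 ± 0.10 and Hoxb6 by 1.24 ± 0.12, with adjusted p of 0.0493, 0.0277 and 0.0493. In WT total RNA Hoxb7 read 10.03 and 9.65, and in KI 7.64 and 7.65, which is the bottom of the signal range. Thbd, which encodes the anticoagulant receptor thrombomodulin, decreased by 1.68 ± 0.12 (adjusted p = 0.0277).

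Genes higher in KI total RNA were Gpx7, a peroxidase of the endoplasmic reticulum (1.90 ± 0.18, adjusted p = 0.0493), and Nppb, which encodes a natriuretic peptide (1.82 ± 0.17, adjusted p = 0.0493). Irf7, a transcription factor of the interferon response, rose by 1.22 ± 0.10 (adjusted p = 0.0468). Foxf1, a transcription factor of mesenchyme, rose by 1.08 ± 0.09 and Hoxc10 by 0.85 ± 0.08 (adjusted p = 0.0493 for each). These 10 genes, 5 higher and 5 lower, were all that passed in limma, and 801 had an unadjusted p under 0.05. The arrays of KI and WT did not overlap for 31.9% of genes, where chance gives 33.3%.

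By list, 1 of 18 measured Hox genes rose and 4 fell in KI total RNA; adjusted over the list alone, 2 rose and 8 fell. The Hox median log2 fold change was -0.41 (camera adjusted p = 7.1e-05; adjusted p = 0.423 with an estimated correlation). Of 30 interferon-response genes, 1 rose over all genes and 1 adjusted over the list alone, and 27 had a positive fold change. Their median was 0.56 (camera adjusted p = 4.9e-11; adjusted p = 0.645 with an estimated correlation), and Isg15, a ubiquitin-like protein, read 2.47 without passing. Of 26 genes of the ATF4 stress response, 0 passed in limma over all genes, 0 adjusted over the list alone and 5 at unadjusted p under 0.05, with a median of 0.33 (camera adjusted p = 1.11e-06; adjusted p = 0.645 with an estimated correlation). Aars, an alanyl-tRNA synthetase, read 1.05 and Herpud1, which acts in protein degradation at the endoplasmic reticulum, 0.95. Of 65 genes of oxidative phosphorylation, 51 had a negative fold change, 0 passed in limma over all genes or adjusted over the list alone and 14 had an unadjusted p under 0.05, with a median of -0.22 (camera adjusted p = 0.000237; adjusted p = 0.645 with an estimated correlation).

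Markers of myofibroblasts, the contractile form of fibroblasts, had a median of 0.47 over 9 measured genes (camera adjusted p = 0.000885; adjusted p = 0.423 with an estimated correlation). Over all genes 0 passed in limma (3 at unadjusted p under 0.05); adjusted over the list alone 3 rose and 0 fell. Smooth muscle actin gamma, Actg2, read 3.08, the smooth muscle protein gene Smtn 0.86 and the tropomyosin gene Tpm2 0.84. The other probes read 0.71 and 0.37 for Smtn and 0.05 and -0.07 for Tpm2. Of 26 matrix genes 0 passed over all genes in limma (10 at unadjusted p under 0.05), while 1 rose and 1 fell adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.000829; adjusted p = 0.423 with an estimated correlation), with 1.06 for the collagen gene Col4a1 and -1.97 for the thrombospondin gene Thbs2. The study's 6 targets had a median of -0.85 (camera adjusted p = 0.185; adjusted p = 0.773 with an estimated correlation), and 0 passed in limma over all genes, adjusted over the list alone or at unadjusted p under 0.05. The study chose them on these samples, so their direction is not independent evidence.

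The array labelled WT total replicate 2 stood apart from the other WT arrays in genes chosen after their values were seen. The chemokine gene Ccl7 read 8.47 there, 12.45 in WT total replicate 1, and 8.76 and 8.60 in KI total RNA. The matrix proteoglycan gene Dcn read 8.09 there against 11.91 in WT total replicate 1, and Crip2 read 12.14 against 7.93. Without that array WT total RNA rested on 1 array, with no spread of its own. The array was singled out after such genes were seen to differ there. Calls without a single array, set below against the 10 genes passing with all arrays, take the missing spread from the other groups. With all arrays Ccl2 and Ccl7 read -1.3 and -1.78 in KI against WT, and without WT total replicate 2 -3.01 and -3.77. The interferon-response median was then 0.40 with 0 members passing (camera adjusted p = 0.000207), the median of the study's targets -1.37 with 2 lower (7.77e-06) and that of Hox genes -0.13 with 4 lower (0.00643). Ribosomal protein genes had a median of -0.20 (0.00313) and oxidative phosphorylation genes -0.39 with 2 lower (4.98e-06). For these 5 lists without that array, the adjusted p with an estimated correlation was 0.725, 0.273, 0.705, 0.721 and 0.273. Without WT total replicate 1, 10 passed of which 1 was among the 10; without either WT polysomal array 4 passed; without KI total replicate 1 or 2, or KI polysomal replicate 1 or 2, 0 passed in limma, with 702, 1246, 649 and 649 at unadjusted p under 0.05. The call of oxidative phosphorylation ended without WT total replicate 1 (camera adjusted p = 0.0968) and that of the stress response without KI total replicate 1 (0.219). By fry, which tests whether a list's genes move on balance one way, 1 list passed in total RNA, the Hox genes (fry adjusted p = 0.00905); interferon-response genes had 0.305 and stress-response genes 0.526. With the replicate number as a block 5 of the 10 genes passed again, namely Hoxb7, Hoxb4, Hoxb2, Thbd and Nppb.

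**Figure D1:**
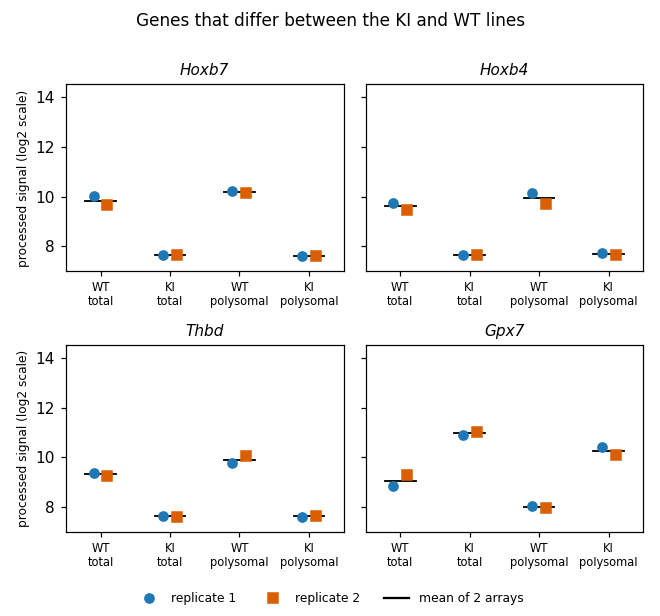
Signal of Hoxb7, Hoxb4, Thbd and Gpx7 on each array (vertical axis, processed signal on a log2 scale) by line and type of RNA; points are arrays and bars the mean of 2. Hoxb7 reads between 9.65 and 10.24 on the 4 WT arrays and between 7.62 and 7.65 on the 4 KI arrays, and Gpx7 is higher in KI in both types of RNA.

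KI against WT in heavy polysomal RNA asked which mRNAs differed among those being translated by several ribosomes. Hoxb7 fell by 2.58 ± 0.14 (adjusted p = 0.00826), Thbd by 2.27 ± 0.12 (adjusted p = 0.00826) and Hoxb4 by 2.23 ± 0.17 (adjusted p = 0.0304), again to the bottom of the range. Gpx7 rose by 2.26 ± 0.18 (adjusted p = 0.0304). Xlr4a, of an X-linked gene family, rose by 2.23 ± 0.14 (adjusted p = 0.0151) and read 7.62 and 7.64 in WT against 9.89 and 9.83 in KI. These 5 genes, 2 higher and 3 lower, were all that passed in limma, with 1013 at an unadjusted p under 0.05, and the arrays of KI and WT did not overlap for 52.5% of genes, where chance gives 33.3%. Next by p, and not passing (adjusted p = 0.0529), were Eif2s3y at 1.89, the VEGF receptor gene Flt1 at 1.26, Wnt5a at 0.84, the kinase gene Frk at -0.86 and Arhgap22 at -1.73. The Y-linked Eif2s3y, which encodes a subunit of the initiation factor eIF2, read 7.64 and 7.64 in WT and 9.47 and 9.60 in KI.

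The study's 6 targets all had a negative fold change in polysomal RNA. The monocyte chemokine genes Ccl7 and Ccl2 read -3.59 (adjusted p = 0.322) and -2.60 (adjusted p = 0.409), and the apoptosis inhibitor gene Birc2 -2.42 (adjusted p = 0.312). The matrix metalloproteinase gene Mmp3 read -1.94, the lymphatic growth factor gene Vegfc -1.52 and the NF-kappaB inhibitor gene Nfkbia -1.15. Over all genes 0 passed in limma, and 6 had an unadjusted p under 0.05. Adjusted over the list alone 6 fell, which is not independent evidence because the study chose them on these samples. Their median was -2.18 (camera adjusted p = 9.32e-05; adjusted p = 0.361 with an estimated correlation). Among 20 genes activated by NF-kappaB, a factor of inflammation, 0 passed over all genes in limma (8 at unadjusted p under 0.05) and 1 fell adjusted over the list alone. Their median was -0.36 (camera adjusted p = 0.00654; adjusted p = 0.361 with an estimated correlation), with -0.86 for Nfkb2 and -0.74 for Tnfaip3. Nfkbia and Birc2 are in the NF-kappaB list and among the study's targets, so these lists are not separate evidence. The probe for Eif4e, which cannot show the point mutation and lies near the bottom of the range in total RNA, read -0.79 (adjusted p = 0.0747).

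**Figure D2:**
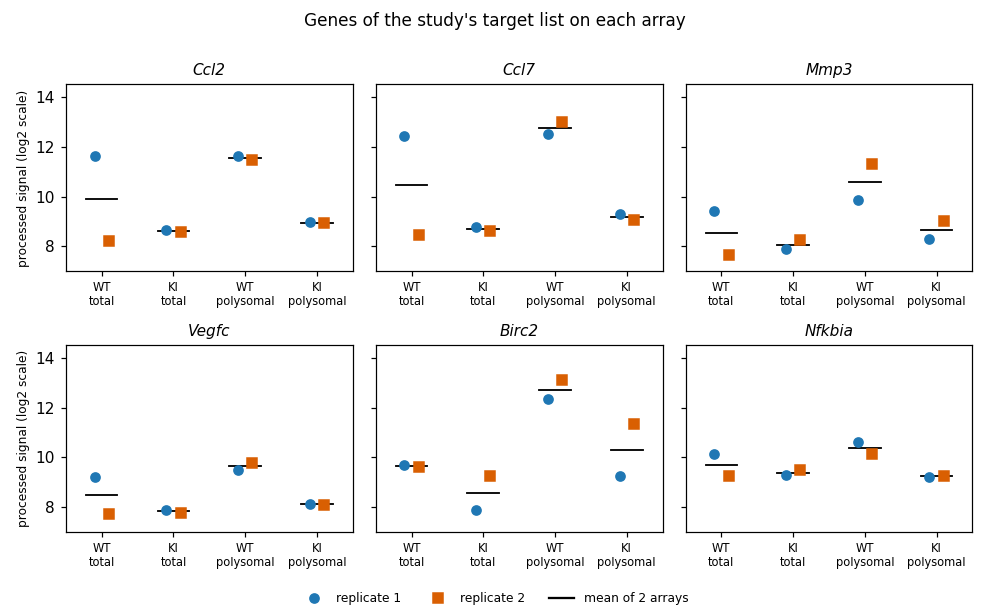
Signal of the study's 6 targets on each array (vertical axis, processed signal on a log2 scale) by line and type of RNA; points are arrays and bars the mean of 2. Ccl2, Ccl7, Mmp3 and Vegfc are lower on the array labelled WT total replicate 2 than on the other 3 WT arrays; Ccl2 reads 8.21 there and 11.63, 11.63 and 11.47 on the others.

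mRNAs of ribosomal proteins and of initiation factors had negative medians in KI polysomal RNA. Of 55 ribosomal protein genes, 49 had a negative fold change, with a median of -0.25 (camera adjusted p = 2.17e-05; adjusted p = 0.464 with an estimated correlation), as with -0.67 for Rpl19. Of 29 initiation factor genes 0 passed over all genes in limma (5 at unadjusted p under 0.05). Adjusted over the list alone 1 fell, and it was Eif4e, the targeted gene. Its probe lay at the bottom of the range in KI and in total RNA of WT. The list's median was -0.14 (camera adjusted p = 0.02, and 0.243 with an estimated correlation). Genes of oxidative phosphorylation had a median of -0.14 (camera adjusted p = 0.0378; adjusted p = 0.547 with an estimated correlation). For ribosomal proteins and oxidative phosphorylation 0 genes passed in limma over all genes and 0 adjusted over the list alone, with 9 and 6 at unadjusted p under 0.05. The list of 18 measured mRNAs held to be sensitive to eIF4E, such as those of cyclins and Myc, had a median of 0.10 (camera adjusted p = 0.426; adjusted p = 0.61 with an estimated correlation).

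The stress-response list had a median of 0.48 in polysomal RNA (camera adjusted p = 4.45e-06; adjusted p = 0.464 with an estimated correlation), with 0 passing over all genes in limma (10 at unadjusted p under 0.05) and 2 higher adjusted over the list alone. Aars read 1.23 and Herpud1 1.17. Relative to the mean of all arrays, the list's mean signal was 0.48 in KI and -0.46 in WT polysomal replicate 1, but -0.02 and -0.13 in replicate 2. Matrix genes had a median of 0.65 (camera adjusted p = 0.000246; adjusted p = 0.243 with an estimated correlation). In limma 0 matrix genes passed over all genes (13 at unadjusted p under 0.05), and 6 rose and 3 fell adjusted over the list alone. The collagen gene Col4a2 read 1.97, and the matrix genes Thbs2 and Fbln1 -2.94 and -1.17. The other Fbln1 probe read -0.43. Myofibroblast markers had a median of 0.31 (camera adjusted p = 0.000137; adjusted p = 0.243 with an estimated correlation), with 0 passing over all genes in limma (5 at unadjusted p under 0.05), 4 higher adjusted over the list alone, and Actg2 at 4.66. Of 18 Hox genes 2 fell over all genes, and 2 rose and 8 fell adjusted over the list alone; the median was -0.10 (camera adjusted p = 0.00044; adjusted p = 0.243 with an estimated correlation).

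Interferon-response genes had a median of 0.11 in polysomal RNA (camera adjusted p = 0.213; adjusted p = 0.825 with an estimated correlation). The WT polysomal arrays differed there, with replicate 1 apart from the other polysomal arrays. Relative to the mean of all arrays, the list's mean signal was -0.40 in WT polysomal replicate 1, 0.40 in WT polysomal replicate 2, and 0.35 and 0.13 in KI. Of the 3 measured sex-linked genes 0 passed over all genes in limma (2 at unadjusted p under 0.05) and 2 rose adjusted over the list alone (median 0.34, camera adjusted p = 0.000321; adjusted p = 0.243 with an estimated correlation), and with no filter on dim probes the list's camera adjusted p was 0.0833. The count of passing genes was 56 without either WT total array, 2 without WT polysomal replicate 1, and 0 in limma without WT polysomal replicate 2 or KI polysomal replicate 1 or 2 (659, 623 and 828 at unadjusted p under 0.05). Without WT total replicate 1, and equally without replicate 2, which enter only through the shared spread, Ccl2 (adjusted p = 0.00648), Ccl7 (adjusted p = 0.0129) and Vegfc (adjusted p = 0.0292) passed. Among lists, camera's adjusted p became 0.0776 and 0.0679 for initiation factors without WT polysomal replicate 2 and KI polysomal replicate 1 and 0.13 with only the brightest probes by mean, 0.0723 for NF-kappaB without KI polysomal replicate 2, and 0.351 and 0.108 for oxidative phosphorylation without WT polysomal replicate 1 and KI polysomal replicate 2. By fry 7 lists passed in polysomal RNA, with adjusted p of 0.00608 for 3 endothelial markers, 0.00896 for Hox and for sex-linked genes, and 0.0394 each for initiation factors, matrix genes, myofibroblast markers and neural markers. The study's targets (0.0892), genes activated by NF-kappaB (0.0658), ribosomal protein genes (0.343), stress-response genes (0.315) and oxidative phosphorylation (0.462) did not pass by fry.

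Across the tested genes, which are not independent replicates, the KI against WT fold changes in total and polysomal RNA correlated at 0.72 (Pearson) and 0.63 (Spearman). They had the same sign for 72.7% of genes. Gpx7 passed as higher in both types of RNA, and Hoxb7, Hoxb4 and Thbd passed as lower in both.

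Polysomal loading asked whether the share of an mRNA on heavy polysomes, relative to its total level, differed between KI and WT. The genes with the smallest p did not pass, and the adjusted p was 1 for each. Arhgef18, which read between 10.01 and 10.90 on the 8 arrays, had a loading difference of 0.77 ± 0.13. For the others at least 1 line lay at or near the bottom of the signal range. KI did so in both types of RNA for Hoxb2 (1.09), Eif4e (-0.72) and Pcdh20 (-0.51), and WT for Xlr4a (1.24), Eif2s3y (1.36), Irf7 (-0.97) and Foxf1 (-0.65). These values cannot compare loading between the lines. Eif4e and Pcdh20 lay at the bottom in WT total RNA too, so their values rest on WT polysomal RNA alone. Frk (-0.82) and Bicc1 (0.57) lay near the bottom in total RNA of both lines. In limma 0 genes passed, with 199 at an unadjusted p under 0.05. These were 2.3% of genes, less than that threshold gives by chance. The polysomal minus total differences of KI and WT did not overlap for 28.7% of genes, where chance gives 33.3%. In the alternative model that regressed polysomal on total signal 0 passed as well, with 1164 at an unadjusted p under 0.05, but that model recovered 0% of the changes in simulated data.

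Of the lists, the study's targets had a median loading difference of -1.33 (camera adjusted p = 0.00112; adjusted p = 0.647 with an estimated correlation), and in limma 0 of them passed over all genes, adjusted over the list alone or at unadjusted p under 0.05. They are not independent evidence, as the study chose them on these samples. The list of genes activated by NF-kappaB shares Nfkbia and Birc2 with them. Interferon-response genes had a median of -0.47 (camera adjusted p = 3.96e-09; adjusted p = 0.667 with an estimated correlation), with 1 lower adjusted over the list alone. Ribosomal protein genes had a median of -0.15 (camera adjusted p = 4.84e-05; adjusted p = 0.667 with an estimated correlation), genes activated by NF-kappaB -0.22 (camera adjusted p = 0.00122; adjusted p = 0.48 with an estimated correlation) and initiation factor genes -0.09 (camera adjusted p = 0.0117; adjusted p = 0.408 with an estimated correlation). The 3 sex-linked genes had a median of 0.30 (camera adjusted p = 5.16e-05; adjusted p = 0.408 with an estimated correlation), with 1 higher adjusted over the list alone; Eif2s3y and Kdm5d among them lay at the bottom of the range in WT. By fry 0 of these 6 lists passed, with adjusted p of 0.0936 for sex-linked genes and 0.836 for each of the others, and 1 other list did, the endothelial markers (0.04). mRNAs held to be sensitive to eIF4E had a median of 0.07 (camera adjusted p = 0.659; adjusted p = 0.818 with an estimated correlation).

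The median loading difference of the study's targets rested largely on the array labelled WT total replicate 2. The polysomal minus total median of the study's targets was 3.39 in WT replicate 2, and 0.37, 0.36 and 0.39 in WT replicate 1 and KI replicates 1 and 2. For interferon-response genes it was 1.15 in WT replicate 2 against -0.08, -0.26 and -0.10. Without that array the loading median was -0.28 for the study's targets (camera adjusted p = 0.764), 0 for ribosomal protein genes (0.981), -0.15 for genes activated by NF-kappaB (0.21) and -0.07 for initiation factors (0.0879). It was -0.32 for interferon-response genes, 0.26 for sex-linked genes and 0.21 for oxidative phosphorylation (0.14 with all arrays). For interferon-response genes the fit kept WT polysomal replicate 2 without its total partner. Their mean signal was 0.40 in that polysomal array and -0.27 in WT total replicate 1. The complete pairs had medians of -0.08 in WT replicate 1, and -0.26 and -0.10 in KI. The -0.32 therefore cannot show that a loading difference remained without WT total replicate 2. Ccl2 and Ccl7 then read 0.41 and 0.18, and Birc2 -1.32 (adjusted p = 0.999 for each). Without WT total replicate 1, which left 1 array of WT total RNA, Ccl2 read -3.02. Without KI total replicate 1 the camera adjusted p was 0.459 for ribosomal protein genes and 0.0931 for genes activated by NF-kappaB, and without WT polysomal replicate 2 the camera adjusted p of the interferon list was 0.0637. For initiation factors it was 0.125, 0.117, 0.0558 and 0.0907 without WT total replicate 1, KI total replicate 2, WT polysomal replicate 2 and KI polysomal replicate 1, and 0.101 with only the brightest probes by mean.

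**Figure D3:**
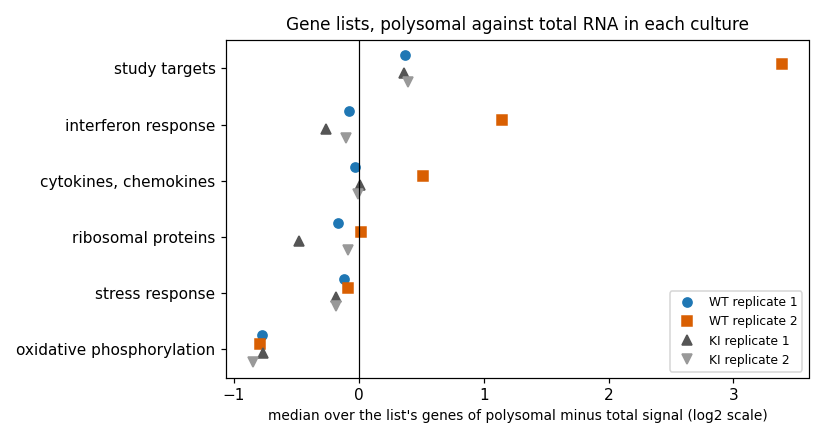
Median over each list's genes of polysomal minus total signal (horizontal axis, log2 scale) for 6 gene lists (vertical axis); each point is 1 culture. For the study's targets WT replicate 2 stands at 3.39 and the other cultures between 0.36 and 0.39, whereas for oxidative phosphorylation the 4 cultures lie between -0.85 and -0.77.

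Polysomal against total RNA in WT asked which mRNAs were carried by heavy polysomes more or less than the average mRNA. Among the genes with the largest rise, Hnrnph1, a splicing regulator, rose by 3.36 ± 0.15 (adjusted p = 0.000565) and Luc7l3, a splicing factor, by 3.52 ± 0.22 (adjusted p = 0.000803). Oxct1, an enzyme of ketone body use, rose by 3.45 ± 0.29 (adjusted p = 0.00164). Nap1l1, a histone chaperone, rose by 3.33, G3bp2, a stress granule protein, by 3.21 and Rbbp7, a histone-binding protein, by 2.98. The other probes read 2.59, 0.78, 1.22 and 3.27 for Hnrnph1, 1.99 and 1.86 for Luc7l3, and 1.96 for Nap1l1. For G3bp2 they read 1.49 and 2.13, and for Rbbp7 2.82, 2.83 and 0.68. Msantd4 (4.13 ± 1.02), the inflammatory caspase gene Casp4 (4.08 ± 0.71), Dcn (3.97 ± 1.13) and Birc2 (3.09 ± 0.77) passed too, with adjusted p of 0.0256, 0.00889, 0.0386 and 0.0261. Their other probes read 2.99 and 0.6 for Casp4, 3.72 for Dcn, and 1.99 and 2.21 for Birc2. The difference between the cultures was wide for some: Dcn differed by 1.98 in WT replicate 1 and 5.96 in replicate 2, and Casp4 by 2.48 and 5.67. Without WT polysomal replicate 2 the adjusted p was 0.148 for Dcn, 0.132 for Birc2, 0.12 for Msantd4 and 0.0539 for Casp4. Without WT polysomal replicate 1 it was 0.128 for Dcn, 0.0898 for Msantd4 and 0.073 for Birc2, and without WT total replicate 2 it was 0.1 for Msantd4 and 0.0993 for Birc2. For Birc2 it was 0.0708 without WT total replicate 1, and for Dcn 0.0662 without either KI total array and 0.0678 without either KI polysomal array.

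Among the genes with the largest fall, Tmsb10, an actin-binding peptide, decreased by 3.68 ± 0.14 (adjusted p = 0.000565). Gpx4, which reduces lipid peroxides, fell by 3.05 ± 0.15 (adjusted p = 0.000565), and Ndufa3 of respiratory complex I by 3.13 ± 0.13. The other probes read -0.94 for Gpx4 and -1.89 and -3.57 for Tmsb10. Cox8a of cytochrome oxidase fell by 2.92 ± 0.17 (adjusted p = 0.000706). Bola2 fell by 3.26, Ost4 by 3.11, Tmem256 by 3.07, Abhd17a by 3.03, Metrn by 2.94 and Cmtm4 by 2.93.

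Of 65 genes of oxidative phosphorylation, 4 rose and 41 fell, and 6 rose and 43 fell adjusted over the list alone. Their median was -0.86 (camera adjusted p = 2.79e-08; adjusted p = 0.727 with an estimated correlation), with Cox6b1 at -2.83, Atp5j2 at -2.55 and Cox7c at -2.45. Of 29 cell cycle genes 12 rose and 2 fell, and 13 rose and 3 fell adjusted over the list alone. Their median was 0.68 (camera adjusted p = 0.015; adjusted p = 0.727 with an estimated correlation), with the replication helicase genes Mcm4 at 2.60 and Mcm6 at 2.15 and the topoisomerase gene Top2a at 2.27. The other Mcm4 probes read 0.41 and 0.37, and those of Mcm6 2.35, 1.97 and 0.27. Of 29 initiation factor genes 14 rose and 3 fell, and 15 rose and 3 fell adjusted over the list alone (median 0.36, camera adjusted p = 0.17; adjusted p = 0.727 with an estimated correlation). Eif2s3x read 2.53, and Mknk2, which encodes one of the kinases of eIF4E, -1.52. Of 55 ribosomal protein genes 5 rose and 15 fell, over all genes and adjusted over the list alone (median -0.06, camera adjusted p = 0.585; adjusted p = 0.988 with an estimated correlation), with Rps27 at -1.84 and Rpl39 at -1.43. Of 15 chaperones of the endoplasmic reticulum 5 rose and 0 fell in limma, over all genes and adjusted over the list alone (median 0.28, camera adjusted p = 0.0923; adjusted p = 0.988 with an estimated correlation), among them Pdia3 at 2.85 and Hsp90b1 at 2.48.

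In WT 3349 genes passed, 1859 higher and 1490 lower in polysomal RNA, and 2697 of the calls kept a change of at least 1.5-fold. With the culture as a fixed block, for the pairing of total and polysomal RNA, 3606 passed. By fry 4 lists passed in WT, with adjusted p of 0.00469 for oxidative phosphorylation and cell cycle genes, 0.00635 for initiation factors and 0.0276 for chaperones. Arrays of the types of RNA did not overlap for 73.5% of genes, where chance gives 33.3%. The count was 2031 without WT total replicate 2, 1708 without WT polysomal replicate 1 and 1407 without WT polysomal replicate 2.

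In KI the same comparison gave 3278 passing genes, 1897 higher and 1381 lower in polysomal RNA. Genes of oxidative phosphorylation again fell as a list: 4 rose and 35 fell, and 5 rose and 38 fell adjusted over the list alone. Their median was -0.80 (camera adjusted p = 9.75e-08; adjusted p = 0.937 with an estimated correlation). Of the cell cycle genes 12 rose and 2 fell, and 13 rose and 2 fell adjusted over the list alone (median 0.61, camera adjusted p = 0.0125; adjusted p = 0.937 with an estimated correlation). Of the ribosomal protein genes 5 rose and 18 fell, over all genes and adjusted over the list alone (median -0.27, camera adjusted p = 0.0336; adjusted p = 0.937 with an estimated correlation). Their median polysomal minus total difference was -0.48 in KI replicate 1 and -0.09 in KI replicate 2. The Eif4e probe read 0.04 here and 0.76 in WT (adjusted p = 0.00376), a difference that did not pass in the test of loading, with KI, and total RNA of WT, at the bottom of the range. By fry 7 lists passed in KI, among them oxidative phosphorylation and cell cycle genes (adjusted p = 0.00433 for each), while ribosomal protein genes did not pass (0.127). Across genes the WT and KI differences correlated at 0.95 (Pearson) and 0.93 (Spearman). Of the passing genes 1570 were higher and 1174 lower in both lines, and 0 passed in opposite directions in limma; independent lists would share 399.3 and 233. With the culture as a fixed block, for the pairing of RNA types, 3530 passed in KI. Without KI polysomal replicate 1, 1994 passed, and without KI polysomal replicate 2, 1414.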

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

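The tests of the library labelled WT total replicate 2 and of the interferon-response genes, and the list tests without single arrays, were chosen only after the results were seen.

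The KI against WT effect differed between polysomal and total RNA, in the test of loading with the preset correlation, for 6 gene lists. The median differences were -1.33 for the study's targets, -0.47 for interferon-response genes, -0.22 for genes activated by NF-kappaB, -0.15 for ribosomal protein genes, -0.09 for initiation factor genes and 0.30 for sex-linked genes, of which Eif2s3y and Kdm5d lay at the bottom of the signal range in WT. With an estimated correlation 0 of the 6 passed, with adjusted p between 0.408 and 0.667, and by fry 0 passed, with adjusted p of 0.0936 for sex-linked genes and 0.836 for the others. Without WT total replicate 2 the medians were -0.28 for the study's targets (camera adjusted p = 0.764), 0 for ribosomal protein genes (0.981), -0.15 for genes activated by NF-kappaB (0.21) and -0.07 for initiation factors (0.0879). Those of interferon-response and sex-linked genes were -0.32 and 0.26. The -0.32 came from a fit that kept WT polysomal replicate 2 without its total partner. In the complete pairs the median polysomal minus total difference of interferon-response genes was -0.08 in WT replicate 1. It was -0.26 and -0.10 in KI replicates 1 and 2. The study's targets were chosen on these samples and are not independent evidence. Nfkbia and Birc2 among them are also in the list of genes activated by NF-kappaB. The gene Arhgef18 had opposite KI against WT differences in total and polysomal RNA, with a loading difference of 0.77; the opposition itself was not tested, and the loading difference did not pass (adjusted p = 1). Probes with no gene symbol, which the comparisons did not use, also passed: 1 of 754 in KI against WT total RNA and 4 in polysomal RNA.

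The library labelled WT total replicate 2 had Ccl2, Ccl7, Dcn and Crip2 near their level in KI total RNA, unlike the other WT libraries. Of 40 genes that separated the lines by 1 log2 unit on the other arrays, 35% lay nearer the WT level. The 95% exact interval was 20.6 to 51.7, but it counts genes as independent, which they are not. This share was 76.5 to 100% in the other WT and at most 11.1% in the KI libraries. Those shares are not a like benchmark: their genes, 11 to 18 per library, had to separate the lines with WT total replicate 2 included. At a gap of 0.5 the share in that library was 36.2%, not apart from the 40% of KI polysomal replicate 2. At a gap of 1.5 it was 56.2% of 16 genes (29.9 to 80.2), against at most 12.5% in the KI libraries. A KI library under a wrong label is argued against by genes at background in all KI libraries. Such genes were chosen without this library, as those expressed in the other WT libraries. Of these 12 genes 6 lay within 0.5 log2 units of WT total replicate 1, among them Hoxb7 at 9.65, Hoxb4 at 9.48 and Thbd at 9.27. However, 5 of the 12 lay at background in it. A mixture with KI RNA cannot exceed both lines, yet 6 genes lay more than 1.5 log2 units above all the other arrays, against at most 2 in any other library, and it would dilute genes expressed in WT only alike, yet over 12 such genes the SD of the log2 shortfall below WT total replicate 1 was 0.77 (95% bootstrap interval 0.51 to 0.92), against 0.24 between the WT polysomal replicates, with Adh7 at background (7.60); for genes at KI-like levels a mixture cannot be told apart, as the median shortfall of 3.03 below the KI level rests on 2 genes. A culture or line other than that of the other WT libraries may be the source, but the profile over runs of neighbouring genes cannot decide this. The total profile of replicate 1 correlated with the polysomal one at 0.87 and that of replicate 2 at 0.32, a gap of 0.55. With the KI partners exchanged, the values were 0.69 for WT total replicate 1 and 0.29 for replicate 2. A KI library or a share of KI RNA would lower this correlation too. The profile was also chosen after the library was seen to differ.

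Interferon-response genes were lower in that library than in its polysomal partner, with a median polysomal minus total difference of 1.15, where random lists had a median of 0.03 and an SD of 0.18. Both libraries differed from replicate 1: relative to the mean of all arrays, the list's mean signal was -0.80 in total RNA of replicate 2 and -0.27 in replicate 1, and 0.40 and -0.40 in polysomal RNA. Ribosome loading in WT cells would show in replicate 1 too, where the difference was -0.08, so the tables argue against it as a feature of WT. An interferon state that differed between the cells behind the libraries may account for the gap, as a hypothesis: Usp18 read 7.68 in total and 11.08 in polysomal RNA of replicate 2, and 8.71 and 8.68 in replicate 1, with no biological difference between the experiments named in the labels to test.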

How the results depend on the processing

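Quantile normalization over all arrays and the list tests without single arrays, with either correlation, were chosen after seeing the data; the other alternatives were planned. Of the counts, pooled over all comparisons, 73 stayed within 1.5 times their reported value and 30 did not. Loading counts of 0 were among those that stayed. The counts for KI against WT in total and in polysomal RNA moved more often than those for polysomal against total RNA. Of the values for single genes, 1282 kept direction and side of the threshold, 135 lost and 47 gained the call, and 10 reversed. Of those for lists called by camera in the reported setting, 353 kept theirs, 85 lost the call and 0 reversed. Lists without that call were left out of this tally, so calls gained by a list were not counted.

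In total RNA the count of 10 became 16 with quantile normalization within each RNA type, 18 with the mean of a gene's probes, 0 with only the arrays compared (457 at unadjusted p under 0.05) and 55 with variance trend and robust; the replicate block gave 9, of which 5 were among the 10. In polysomal RNA the count of 5 became 9 with no filter, 28 with only the brightest probes by mean, 15 with every probe, 8 with only the arrays compared, 73 with trend and robust, 13 with the replicate block and 15 with the culture as a random block. Leaving out each array gave 0 to 40 genes in total RNA, 0 to 56 in polysomal RNA, 0 to 7 for loading, 1407 to 3481 in WT and 1414 to 3533 in KI. An arm left with 1 array was assumed to vary like the others. The replicate block gave 0 for loading, 3790 in WT and 3690 in KI.

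The regression model of loading reversed Arhgef18 (adjusted p = 0.942), Hoxb2 (0.658) and Irf7 (0.977). Without WT total replicate 2 loading reversed for Ccl2 and Ccl7 (0.999 for each); leaving out each array gave 0.023 to 1 and 0.0595 to 1. Without WT total replicate 1 the total RNA difference reversed for Ccl2 (0.321), Ccl7 (0.834), Mmp3 (0.911), Nfkbia (0.897) and Vegfc (0.904). Leaving out each array gave ranges of 0.0102 to 0.899, 0.0269 to 0.877, 0.427 to 0.976, 0.251 to 0.948 and 0.0571 to 0.904 for these. Apart from these constructions, the cause was not tested.

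Not run were the background correction with a floor of 16, normexp before median scaling and the exchange of the processed values for the table named non-normalized. Loading has no value with only the arrays compared, and single genes none with every probe. Genes at the bottom of the signal range limit what can be seen.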

Other observations

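The test of the order of genes against array noise was chosen after the result was seen; those of long-range differences and of the genes near Eif4e were written before.

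Among lists for other cell types, KI against WT medians in total and polysomal RNA, with camera's adjusted p, were -0.12 (0.195) and -0.05 (0.955) for 5 epithelial markers, 0.15 (0.21) and 0.21 (0.213) for 6 neural markers, and -0.22 (0.184) and 0 (0.689) for 6 markers of cartilage and bone. The library labelled WT total replicate 2 stood apart here: without it the total RNA medians were -0.01 (0.98) for cartilage and bone and -0.21 (0.664) for epithelium. Relative to the mean of all arrays, the mean signal in it was 0.60 for the first list, with the cartilage collagen Col2a1 at 10.42, and 0.67 for the second. For 3 endothelial markers the medians were -0.11 (0.814) and -0.05 (0.215), although the mean was positive, at 0.09 and 0.38, with Flt1 higher adjusted over the list alone. By fry, endothelial (adjusted p = 0.00608) and neural markers (0.0394) passed in polysomal RNA. The direction of camera was also positive for endothelial markers in both types of RNA and for epithelial markers in polysomal RNA. The 12 fibroblast markers had medians of 0.14 (0.285) and 0.15 (0.402), and in polysomal RNA 1 rose and 2 fell adjusted over the list alone. For each of these lists 0 genes passed in limma over all genes. At unadjusted p under 0.05 there were 2, 1, 0, 1 and 1 genes in total RNA for epithelial, neural, cartilage and bone, endothelial and fibroblast markers, and 0, 3, 0, 1 and 3 in polysomal RNA. Of skeletal muscle markers 2 were measured, too few for a test, with medians of 0.64 and 0.92; Acta1, a skeletal actin, read 1.32 and 1.83, and Myog, a muscle transcription factor, -0.04 and 0.

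Cytokine and chemokine genes had medians of -0.11 (camera adjusted p = 0.852) and -0.27 (0.0514), and of -0.42 and -0.27 without WT total replicate 2. The list holds Ccl2 and Ccl7, which the study chose as targets on these samples, so it is not separate evidence. With an estimated correlation the adjusted p of that list was 0.928 and 0.547, and 0.273 and 0.322 without that array. Apoptosis genes had medians of -0.16 (0.352) and -0.05 (0.192), and p53 targets 0.06 (0.346) and 0.20 (0.213). In polysomal against total RNA of WT, 7 of 18 cholesterol synthesis genes rose and 2 fell, and 8 rose and 3 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.981). Of 14 other mRNAs with a terminal oligopyrimidine tract 6 rose and 1 fell, over all genes and adjusted over the list alone (median 0.40, camera adjusted p = 0.0949), with Hnrnpa1 at 2.41 and Npm1 at 2.29. The other Hnrnpa1 probe read 1.03.

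KI and WT polysomal libraries differed over runs of neighbouring genes in the reference order: adjacent genes correlated at 0.28 in the mean difference, and at 0.20 and 0.29 in replicates 1 and 2. Between the WT polysomal libraries the value was 0.03, but the KI polysomal libraries gave 0.14, the KI total libraries 0.09 and the WT total libraries 0.22. Libraries of 1 line thus reached values like those of KI against WT, so this test cannot decide on array noise. Genes 20 measured genes apart correlated at 0.23 in the mean difference, and at 0.16 and 0.22 in the replicates, where permuted orders reached 0.05, so a copy number or other long-range difference between the lines may contribute. In total RNA the values 20 genes apart were 0.13 and 0.18 for KI against WT, but also 0.12 between the WT total libraries, so such runs are not limited to the comparison of lines. The 40 measured genes nearest to Eif4e had a median absolute difference at the 88.2 percentile of runs of that size, with 0 passing in limma. This lay below the 95th percentile set beforehand for an effect of DNA around the targeted gene, so that prediction was not met. The 95% interval of 53.7 to 96, which was not part of that rule, spans the bound. Such an effect is therefore not excluded.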
